A study of Homo sapiens with 75 samples.

How the data were processed

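RNA from 75 primary bone marrow samples of T-cell acute lymphoblastic leukemia (T-ALL) was sequenced after exome capture, with libraries from the TruSeq RNA Exome kit run on an Illumina NextSeq as 150 bp paired-end reads, per the labels' protocols. Capture by exome probes enriches coding sequence, so a level depends on probe design as well as on RNA amount, and GC content can act on capture and on amplification. The submitters' processing notes name Bowtie2 (version 2), RSEM and the hg38 build. No label gives a subtype, a treatment, a response or a sequencing batch, so all samples formed 1 group. The labels do not say that each sample came from a separate patient, and p-values therefore measure the spread between these samples.

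The deposited table holds log2 CPM (counts scaled to library size) for 7869 genes in 75 columns, each matched to its sample by title. The log base was taken from the values, since powers of 2 of a column sum to between 778632 and 1422810. These sums differ between samples. Removal of genes can only bring a sum below the per-million total of CPM, and the highest sum lies above it. A library scaling step is therefore part of the deposited values. A later removal of genes may also be, and neither is described in the sources used here. The lowest gene median is 3.28 log2 CPM, so genes with a lower median are not in the table analysed here. Such genes can include some of high level in a minority of samples. BCL2 and BCL2L11 were in the plan and are not analysed here, and with them 6 of 16 planned relations, 1 of 3 planned genome-wide fits and its list test. The value -7.56 stands as the lowest in 76 genes. Whole reads could not be recovered from logged estimated counts, so the depth per sample is unknown and no counting interval is given. No 2 samples were near copies of each other, since the highest of 2775 pairwise correlations was 0.94 and the median 0.72.

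GENCODE release 29 on GRCh38, the same assembly as hg38, supplied gene positions and the GC content of transcripts for 7775 genes (98.8%). For each sample a GC slope was computed as the regression slope of its log2 deviations from the gene means on gene GC content, in log2 per 10 percentage points. It ran from -0.63 to 1.08 (SD 0.35), and it is used below as a measure of GC trends between samples, whose origin was not tested.

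Before the data were examined, 22 gene lists, the tests and the rule for named genes were fixed. Every gene was regressed on the level of NR3C1, and separately of IL7R, with limma 3.58.1 in R 4.3.3 (trend and robust variance moderation) and Benjamini-Hochberg adjustment at 0.05. A slope is the change in log2 CPM of a gene per unit of log2 CPM of the receptor gene. The filter on mean log2 CPM above 0 removed 0 genes. In the text, rose and fell mean a positive or negative slope past the threshold. Lists with 3 or more measured members were tested with camera at a preset inter-gene correlation of 0.01. A list score is the mean z score of its members, leaving out the receptor genes. Relations between scores and receptor genes were tested with two-sided permutation tests of Pearson r and Spearman rho (100000 resamples, smallest possible p 1e-05). A measure was to be treated as clustered if a fit with 2 Gaussian components lowered the Bayesian information criterion by more than 10, separated the means by an Ashman D above 2 and left 6 or more samples in each. None of the 24 measures met this, so relations over all samples are given.

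Named genes are the receptor genes and measured list members. To these are added, per fit, the 12 genes with the largest positive and the 12 with the largest negative limma statistic. The last part is the 20 genes with the largest SD among those with mean log2 CPM above 1. Genes on chromosome Y and those of X inactivation were left out of the last 2 parts, and immunoglobulin and T cell receptor segments out of the last. The lists cover glucocorticoid-induced genes, glucocorticoid receptor machinery, STAT5-induced genes, the interleukin-7 receptor pathway, BCL2 family members of both kinds, and early progenitor, cortical thymocyte and mature T cell markers. They also cover T-ALL transcription factor oncogenes, NOTCH1-induced, cell cycle, interferon-induced and handling stress genes, and erythroid, B cell, plasma cell, monocyte, granulocyte precursor, megakaryocyte, NK cell and stromal markers. The NK cell and stromal lists have 0 measured members and are not analysed here. MYC, MCL1 and BCL2L1 each stand in 2 lists.

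The limma step was tested on simulated data with 200 changed genes among 7868. Slopes of 0.6 SD were recovered for 96% of genes with NR3C1 and 98% with IL7R, slopes of 0.3 SD for 24% and 18%, and 4 and 7 other genes were called. The simulated genes varied independently of each other, so these counts of other genes do not give the error for correlated genes. On the real table, 99 shuffled orderings called up to 1192 genes for NR3C1 and 550 for IL7R, with a median of 0 for both. The permutation step found 97% of 100 simulated relations of r = 0.4 and called 4% of 200 null relations. Alternatives fixed in advance were log2(CPM + 1), quantile normalization, covariates for other cell types, cell cycle and the first 2 principal components, other filters, rank-based scores, and fits without 8 samples with most other-lineage signal or without the 2 farthest samples. Covariates for the GC slope, the small RNA share and, for the genome-wide fits, handling stress were chosen after seeing the data, as was a filter at mean log2 CPM 4. All results beside the GC slope are therefore later additions to the plan. NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and scikit-learn 1.9.0 under Python 3.11.15 were used for scores, permutations and mixtures, and matplotlib 3.10.9 for figures.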

Results

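The series asks how glucocorticoids relate to steroid resistance in T-ALL, a leukemia of immature T cells, and in thymocytes. The part analysed here comprises bone marrow transcriptomes of 75 primary T-ALL samples in 1 group. Steroid exposure and response are not analysed here, so the comparisons are relations across samples, anchored on NR3C1, which encodes the glucocorticoid receptor, and on IL7R, which encodes the interleukin-7 receptor alpha chain. Values are log2 CPM, and the sequencing depth behind them is unknown.

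NR3C1 lies on chromosome 5 from 143277931 to 143435512 on the minus strand of GRCh38, and IL7R on the same chromosome from 35852695 to 35879603 on the plus strand. Both are protein-coding genes. NR3C1 averaged 8.05 ± 1.0 log2 CPM (SD, n = 75) with a range from 4.61 to 10.46, and IL7R averaged 6.28 ± 1.48 (SD, n = 75) with a range from 1.34 to 9.30. The median SD over all genes was 0.75, and 307 genes had an SD above 2. Among glucocorticoid-induced genes, TSC22D3 (GILZ, a leucine zipper protein) averaged 7.28 ± 1.42, FKBP5 (a co-chaperone of the receptor) 6.53 ± 1.5, and PER1 (a clock gene) 5.85 ± 1.23, while ZBTB16, a zinc finger transcription factor, was far more spread at 4.28 ± 3.01 (SD, n = 75 each). CD1B, a marker of cortical thymocytes, ranged from -5.40 to 8.39, RAG1, a recombinase gene, from -0.86 to 9.55, and FLT3, a receptor of early progenitors, from -1.21 to 9.49. CD3D, a T cell receptor complex gene, kept a narrower range of 6.57 to 10.49.

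**Figure D1:**
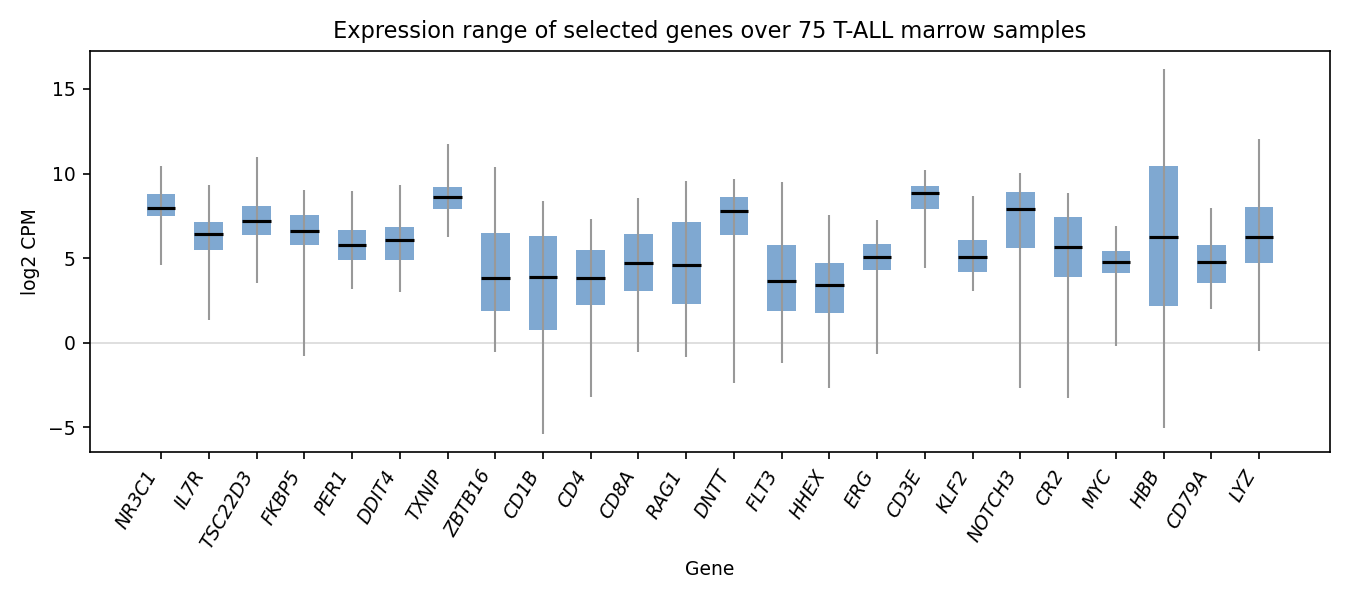
Expression in log2 CPM (vertical axis) of 24 genes (horizontal axis) over 75 T-ALL samples, with lines from the lowest to the highest sample, boxes from the lower to the upper quartile and bars at the median. NR3C1 spans 4.61 to 10.46 and CD1B spans -5.40 to 8.39.

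Among genes with mean log2 CPM above 1, the 20 with the largest SD included CD1B (3.96) and haemoglobin genes, which mark red cell precursors. Their SD was 5.0 for HBB, 4.6 for HBA1 and 4.22 for HBA2. Cadherin-like FAT1 (4.19), the peroxidase PXDN (4.19), ALDH1A2, an enzyme of retinoic acid synthesis (4.35), CSMD1 (4.30), TUSC3 (4.75), ANTXR1 (4.11), PLEKHG4B (4.11), ATRNL1 (3.97), PLCB4 (3.92) and FLG (3.99) were also among the 20. Of the 20 genes only HBB, HBA2, FAT1, CD1B and GSTM1 stayed above the lowest value of the table (-7.56) in all samples. The SDs and ranks of the others depend in part on that value. HBA1, HBA2, the defensin DEFA3 (4.08), the histone gene HIST1H4K (4.96), the pseudogene H3F3AP4 (5.25), F8A1 (4.47), GSTM1 (3.84) and the small RNA SNORD15A (3.77) have near-identical copies or close relatives, so their levels are uncertain.

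A large part of the table varied with NR3C1. Of 7868 genes, 2220 rose and 1558 fell with it (limma, adjusted p under 0.05). The smallest p-values among positive slopes belonged to MTMR6, a phosphoinositide phosphatase (0.55 ± 0.06, SE, n = 75, adjusted p = 1.7e-11), CDK17, a cyclin-dependent kinase (0.78 ± 0.08, adjusted p = 1.7e-11), and SHOC2, a scaffold of RAS-RAF signalling (0.56 ± 0.06, adjusted p = 9.1e-11). SUCO, CUL3, PSME4, REPS1, RB1CC1, ANKRD12, FBXO34, B4GALT1 and STK17B completed the 12 leading positive genes, with slopes from 0.48 to 0.83. Among negative slopes they belonged to AGAP2 (-0.49 ± 0.06, adjusted p = 2.2e-08), SLX1A, a nuclease subunit with a near-identical copy and so an uncertain level (-0.40 ± 0.06), and NUDT22 (-0.41 ± 0.06). TRAPPC12, INO80E, APEH, PAGR1, RFXANK, SLC9A3R1, CTDSP1, FAM207A and ZC3H7B followed, with slopes from -0.58 to -0.30.

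NR3C1 also varied with the GC slope of the samples (Pearson r = -0.57, permutation p = 1e-05; Spearman rho = -0.59, permutation p = 1e-05; both p the smallest possible; r = -0.56 without the 2 farthest samples; adjusted p = 3e-05 and 2.6e-05 over 21 relations). Across genes, which are not independent replicates, the NR3C1 statistic correlated with GC content at r = -0.65. With the GC slope as a covariate, a fit chosen after seeing the data, 609 genes rose and 990 fell, and 505 of the 3778 genes called without it stayed called in the same direction. All 24 genes named above stayed called, each with a slope nearer to 0, as for CUL3 (0.48 to 0.24), REPS1 (0.53 to 0.25), SLC9A3R1 (-0.51 to -0.21) and PAGR1 (-0.57 to -0.18). With the first 2 principal components as covariates the total was 2067.

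Glucocorticoid-induced genes, which the receptor activates when bound by hormone, were split in their relation to NR3C1. Of 18 measured members, 5 rose with NR3C1 and 1 fell, and the counts were also 5 and 1 adjusted over the list alone. Of all 7868 genes 2220 rose and 1558 fell, so the share of members that rose was near that of all genes. The counts of other lists with NR3C1 below are to be read against the same background. CXCR4, a chemokine receptor, rose by 0.67 ± 0.11 (SE, n = 75, adjusted p = 1.8e-06), BTG1, an antiproliferative gene, by 0.43 ± 0.07 (adjusted p = 1.4e-06), and ZFP36L2, an RNA-binding protein, by 0.50 ± 0.12 (adjusted p = 0.00044). TXNIP and FKBP5 rose by 0.43 ± 0.12 (adjusted p = 0.0022) and 0.47 ± 0.16 (adjusted p = 0.015), and the metallothionein gene MT1X fell by 0.31 (SE 0.12, adjusted p = 0.031). TSC22D3 had a slope of 0.16 ± 0.16 (adjusted p = 0.43) and PER1 of 0.26 ± 0.14 (adjusted p = 0.11). As a set, the list did not pass camera (adjusted p = 0.34, and 0.97 with an estimated correlation). It passed upwards with fry (adjusted p = 0.038) and beside the first 2 principal components (camera, adjusted p = 0.00016), where an estimated correlation was not run.

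Beside the GC slope, 10 of the 18 rose and 0 fell. TSC22D3 then had a slope of 0.85 (limma adjusted p = 4.6e-05), PER1 of 0.81 (adjusted p = 1.5e-05), DDIT4, a stress-response inhibitor of mTORC1, of 0.69 (adjusted p = 0.0021), and the slope of MT1X was 0.01. NFKBIA and IRS2 were the other additions. The list passed camera in that fit (adjusted p = 6e-09), but not with an estimated correlation (adjusted p = 0.056).

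**Figure D2:**
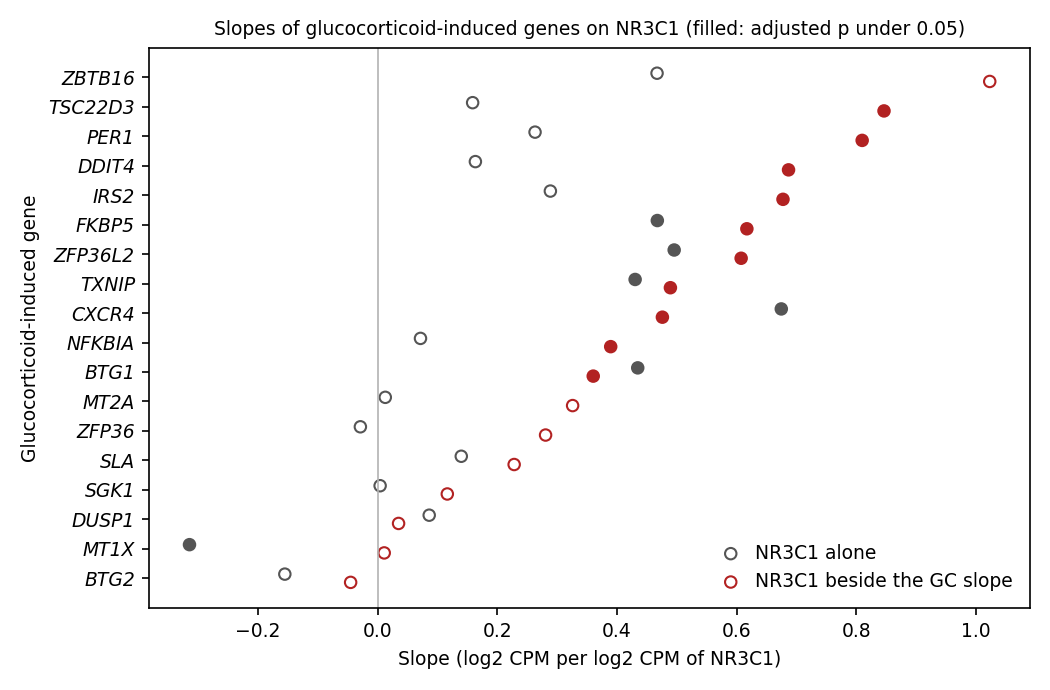
Slopes (horizontal axis, log2 CPM per log2 CPM of NR3C1) of the 18 measured glucocorticoid-induced genes (vertical axis), from fits with NR3C1 alone (grey) and beside the GC slope (red), with filled points for adjusted p under 0.05. The slope of TSC22D3 is 0.16 alone and 0.85 beside the GC slope.

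The score of these 18 genes had r = 0.29 with NR3C1 (permutation p = 0.0126) and rho = 0.25 (permutation p = 0.034), with r = 0.26 without the 2 samples farthest from the NR3C1 median. Adjusted over the 10 relations run, these were p = 0.053 and 0.11, so the relation missed the threshold. The partial r beside the GC slope was 0.51 (permutation p = 1e-05, the smallest possible, adjusted p = 0.0001), and 0.51 without the 2 farthest samples.

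**Figure D3:**
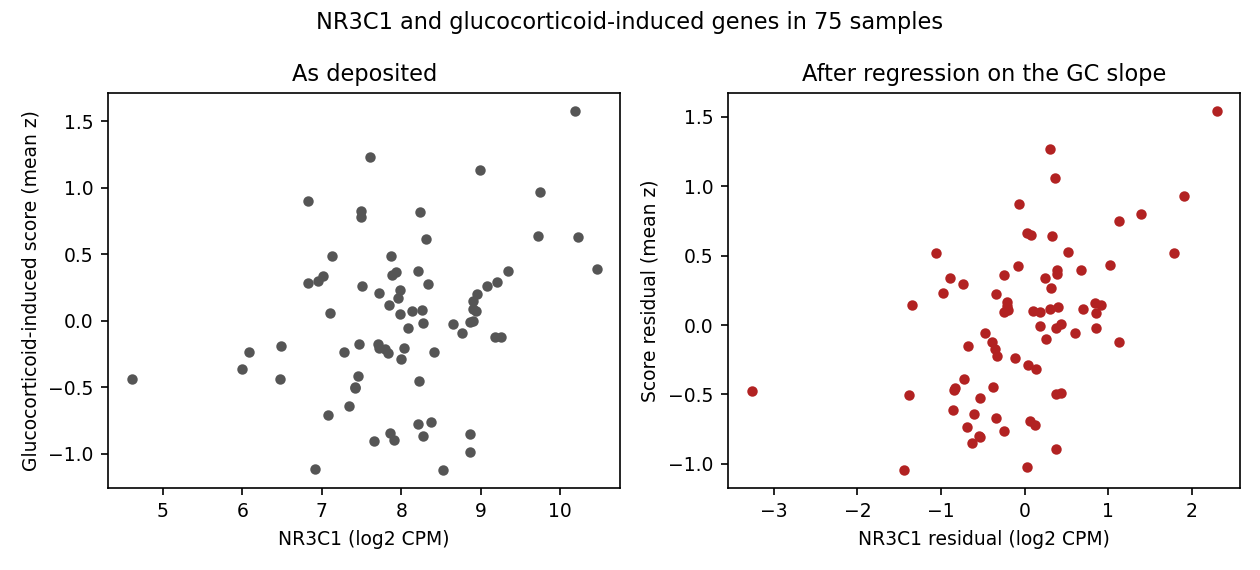
NR3C1 in log2 CPM (horizontal axes) and the mean z score of glucocorticoid-induced genes (vertical axes) in 75 samples (points), as deposited (left) and as residuals after regression on the GC slope (right). The correlation is 0.29 on the left and 0.51 on the right.

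Cofactors of the receptor moved in both directions with NR3C1. Of 16 measured members of the receptor machinery, 6 rose, namely the coactivator genes NCOA1, NCOA2, NCOA3, CREBBP and EP300 and the chromatin remodeling gene ARID1A. NCOA3 had the steepest of these slopes at 0.36 ± 0.09 (SE, adjusted p = 0.00074). The co-chaperone gene FKBP4 (-0.45 ± 0.14, adjusted p = 0.0054) and the remodeling genes SMARCA4 and SMARCB1 fell. Adjusted over the list alone, 6 rose and 6 fell. The set as a whole did not pass camera (adjusted p = 0.96). Beside the GC slope, 1 member, CREBBP, rose and 4 fell, among them FKBP4 and SMARCB1.

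Of 12 mature T cell markers, 0 rose and 4 fell with NR3C1, of which IL32, a cytokine gene, had the steepest slope (-0.90 ± 0.25, adjusted p = 0.0027), followed by CD5, KLF2 and CD52. The list missed the camera threshold (adjusted p = 0.26), and 3 members fell adjusted over the list alone. IL32, CD5 and KLF2 were no longer called beside the GC slope, where 3 members fell. The partial r there was -0.25 for IL32 and -0.22 for CD5, against -0.38 and -0.33 plain. For KLF2 it was -0.07, against -0.34 plain. FLT3 rose by 1.02 ± 0.26 (adjusted p = 0.00099) as the only called gene of 6 early progenitor markers, and 0 of 6 cortical thymocyte markers were called. In the interleukin-7 receptor pathway JAK2 rose (0.33 ± 0.09), while STAT5A (-0.41 ± 0.11), STAT5B, JAK3 and DNM2 fell, 5 of 12 members in all, while 1 rose and 3 fell adjusted over the list alone. None of the 12 was called beside the GC slope, with slopes of 0.01 for JAK2 and -0.19 for STAT5A. Of 22 listed transcription factor oncogenes 3 were measured, namely BCL11B, MYB and MYC, without TAL1, TLX1, TLX3 or the HOXA genes. BCL11B, a T cell regulator, fell by 0.59 (SE 0.16, adjusted p = 0.0019), and MYB joined it adjusted over the list alone. That list passed downwards with fry (adjusted p = 0.018) and not with camera in any setting. The slope of BCL11B was -0.16 beside the GC slope (adjusted p = 0.53). The replication licensing genes MCM2, MCM3 and MCM5 fell among 14 cell cycle genes, and 2 did adjusted over the list alone. MCM3 and MCM5 were no longer called beside the GC slope, though their partial r there was -0.29 each, against -0.36 and -0.26 plain. In that fit the cell cycle list passed camera downwards (adjusted p = 0.02, and 0.98 with an estimated correlation).

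MCL1, a survival gene of both the STAT5-induced and the anti-apoptotic BCL2 family lists, rose by 0.24 (SE 0.10, adjusted p = 0.034), as 1 of 4 and 1 of 2 members, while BCL2L1 in the same 2 lists was not called. Adjusted over the list alone, MCL1 was called in the BCL2 family list and not in the STAT5 list. Of the 2 pro-apoptotic members PMAIP1 rose (0.38 ± 0.15) and BAX fell (-0.15 ± 0.06), also adjusted over the list alone. LZTFL1 rose as 1 of 7 NOTCH1-induced genes and 0 did adjusted over the list alone. OAS3 fell as 1 of 2 interferon-induced genes, FCN1 as 1 of 5 monocyte markers, and GP1BA rose as the single megakaryocyte marker, each also adjusted over the list alone. None of 3 erythroid, 2 B cell, 1 plasma cell and 2 granulocyte precursor markers was called with NR3C1, also adjusted over the list alone. Of the genes in this paragraph GP1BA alone stayed called beside the GC slope. Plain and partial r beside it stayed close for PMAIP1 (0.29 and 0.24), BAX (-0.29 and -0.23) and OAS3 (-0.26 and -0.21). For these genes the lost call does not show that the relation went away. The partial r was nearer to 0 for MCL1 (0.28 and 0.15), LZTFL1 (0.27 and 0.05) and FCN1 (-0.32 and -0.06).

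Handling stress genes, which respond within minutes to hours of sample processing, fell with NR3C1 for 7 of 10 members, the same number adjusted over the list alone. IER2 had a slope of -0.73 ± 0.15 (adjusted p = 4.9e-05) and HSPA1A, a heat shock gene, of -0.73 ± 0.15 (adjusted p = 8.4e-05). It was the only list past camera with NR3C1 (adjusted p = 0.0044, and 0.97 with an estimated correlation). Beside the GC slope 0 of 10 were called, and the adjusted p of camera was 0.84, against 0.11 beside the first 2 principal components and 0.053 beside other cell type scores. HSPA1A and HSPA1B are near-identical, so their separate levels are uncertain.

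IL7R had fewer partners. With it 207 genes rose and 185 fell of 7868. FYN, a Src-family kinase of T cell receptor signalling, rose by 0.23 ± 0.04 (SE, n = 75, adjusted p = 0.00074), ATM, the DNA damage kinase, by 0.32 ± 0.06 (adjusted p = 0.0018), and KLF12 by 0.28 ± 0.06 (adjusted p = 0.0035). IGHV4-34, an immunoglobulin segment (0.59 ± 0.10, adjusted p = 0.00073), and RGPD1 (0.80 ± 0.15) also rose, and each has close relatives, so their levels are uncertain. EXT1, PCGF5, RNF145, MGAT4A, SMC6, STARD4 and SSH2 completed the 12. JARID2, a cofactor of Polycomb repressive complex 2, fell by 0.34 (SE 0.07, adjusted p = 0.0028), and PML, a nuclear body gene, fell by 0.17 (SE 0.03, adjusted p = 0.0033). LRRC8A, ARMC5, MYO18A, CEP85, BCR, SH3GL1, DDAH2, MLXIP, CEL and HLA-C were the others, of which HLA-C is highly polymorphic and CEL has a pseudogene. Without the 2 samples farthest from the IL7R median 100 genes were called, 37 positive and 63 negative. Beside the GC slope 48 were, 31 positive and 17 negative, of which 30 were among the 392. Of the 24 genes named above 9 stayed called beside it, namely IGHV4-34, FYN, ATM, RGPD1, KLF12, EXT1, JARID2, PML and LRRC8A. IL7R had r = -0.32 with the GC slope (permutation p = 0.0053; rho = -0.33, permutation p = 0.0044; r = -0.32 without the 2 farthest samples; adjusted p = 0.008 and 0.0066 over 21 relations).

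Several NOTCH1-induced genes rose with IL7R. Of 11 listed members 7 were measured, without HES1, HEY1, DTX1 or NRARP. Of these 7, 4 rose and 0 fell, and all 7 rose when adjusted over the list alone. CR2, a complement receptor gene, rose by 0.80 ± 0.19 (adjusted p = 0.011), NOTCH3 by 0.74 ± 0.18 (adjusted p = 0.017), MYC by 0.36 ± 0.09 (adjusted p = 0.017) and LZTFL1 by 0.43 ± 0.13 (adjusted p = 0.037). The list passed camera (adjusted p = 0.0001, and 0.11 with an estimated correlation). Beside the GC slope LZTFL1 was no longer called, HES4 was, and the adjusted p of camera was 3.9e-11, and 0.0013 with an estimated correlation. The score had r = 0.51 with IL7R (permutation p = 2e-05) and rho = 0.38 (permutation p = 0.00061), with adjusted p = 0.00072 and 0.011 in a family of 36 score relations chosen after seeing the data. Without the 2 farthest samples r was 0.34 (permutation p = 0.0032).

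**Figure D4:**
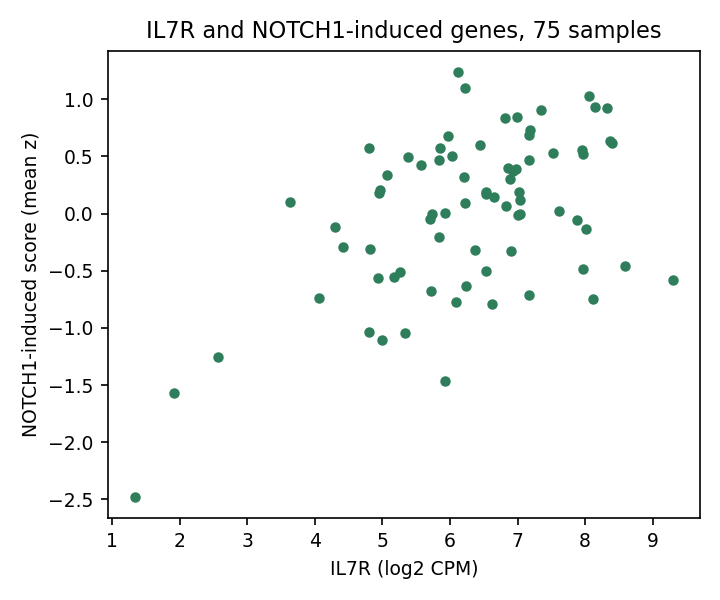
IL7R in log2 CPM (horizontal axis) and the mean z score of 7 NOTCH1-induced genes (vertical axis) in 75 samples (points). The correlation is 0.51, and 0.34 without the 2 samples farthest from the IL7R median.

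Of 24 thymocyte stage markers 3 were called with IL7R, and 0 beside the GC slope. Plain and partial r beside it were 0.38 and 0.30 for CD8A, 0.38 and 0.34 for CD3G, and -0.35 and -0.36 for ERG. The lost calls therefore do not show that these relations went away. CD8A, the CD8 coreceptor gene, rose by 0.56 ± 0.16 (adjusted p = 0.03) as the only call among 6 cortical thymocyte markers, and 4 of them rose adjusted over the list alone, namely CD1B, CD8A, RAG1 and ARPP21. Their score had r = 0.34 with IL7R (permutation p = 0.0031, adjusted p = 0.031 over 10 relations) and rho = 0.25 (permutation p = 0.0295, adjusted p = 0.11). Without the 2 farthest samples r was 0.22 (adjusted p = 0.23), so its call rests on those samples. CD3G rose among 12 mature T cell markers, with CD3E added when adjusted over the list alone, and ERG, a progenitor transcription factor, fell by 0.32 (SE 0.10, adjusted p = 0.043) among 6 early progenitor markers, with HHEX added when adjusted over the list alone. Camera passed for cortical markers (adjusted p = 0.025, 0.28 with an estimated correlation and 0.22 without the 2 farthest samples) but not for mature (0.063) or early markers (0.056), which both passed with fry (0.046 each) and without the 8 samples with most other-lineage signal (0.04 and 0.031). The mature list also passed beside the first 2 principal components (0.002). With the GC slope as a covariate all 3 passed (cortical 5.3e-05, mature 0.0003, early 0.024), and none did with an estimated correlation (0.072, 0.14 and 0.14).

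No member of the interleukin-7 receptor pathway list and none of the few measured STAT5-induced genes rose with IL7R. In the interleukin-7 receptor pathway 0 of 12 members rose and 3 fell, also adjusted over the list alone: the negative regulator SH2B3 (-0.26 ± 0.06, adjusted p = 0.012), STAT5A (-0.25 ± 0.08, adjusted p = 0.048) and DNM2 (-0.13 ± 0.04, adjusted p = 0.042). The list passed camera (adjusted p = 0.039, and 0.28 with an estimated correlation). It did not pass after quantile normalization (0.33), on rank-based normal scores (0.12), without the 2 farthest samples (0.22), or beside the first 2 principal components (0.20) or the cell cycle score (0.053). With the GC slope as a covariate it passed (0.023, and 0.18 with an estimated correlation), while 0 members were called. Of 13 listed STAT5-induced genes 4 were measured, namely PIM1, PIM2, BCL2L1 and MCL1, without CISH or the SOCS genes. These 4 had 0 calls, also adjusted over the list alone, and did not pass camera (adjusted p = 0.79). BTG1 and CXCR4 were the 2 of 18 glucocorticoid-induced genes that rose with IL7R, also adjusted over the list alone. Beside the GC slope 0 of this list did, with a partial r of 0.31 and 0.28 for these 2, against 0.41 and 0.40 plain. That list did not pass camera (adjusted p = 0.87), but passed upwards beside the GC slope (adjusted p = 0.047, and 0.50 with an estimated correlation) and beside the first 2 principal components (0.002). Receptor machinery passed downwards in the same fits (0.038, 0.18 with an estimated correlation, and 0.035). The 3 measured of 22 transcription factor oncogenes passed upwards beside the GC slope (0.017, and 0.076 with an estimated correlation). Cell cycle genes passed downwards beside the 2 components (1.2e-05). Handling stress, erythroid and monocyte lists passed camera downwards (adjusted p = 0.002, 0.031 and 0.039), and none of them did with an estimated correlation (adjusted p = 0.28, 0.28 and 0.39) or beside the GC slope (adjusted p = 0.26, 0.11 and 0.20) or the first 2 principal components (0.19, 0.20 and 0.29). The monocyte list also missed the threshold beside the cell cycle score (0.053) and with fry (0.11). The 3 haemoglobin genes of the erythroid list were called downwards adjusted over the list alone and not over all genes. Of 10 handling stress genes IER2 fell (-0.38 ± 0.11, and -0.14 without a call beside the GC slope), and 0 of 5 monocyte markers were called. The B cell gene CD79A rose by 0.35 ± 0.10 (adjusted p = 0.038) as 1 of 2 members. In the 36 score relations chosen after seeing the data, the B cell score had r = 0.32 with IL7R (permutation test, adjusted p = 0.039). Its rho was 0.22 (permutation test, adjusted p = 0.16), and its partial r beside the GC slope 0.42 (permutation test, adjusted p = 0.0012). MYC, also a transcription factor oncogene, was the only call of that list of 3. For the handling stress, monocyte, B cell and oncogene lists the counts were the same adjusted over the list alone. None of 16 receptor machinery genes was called with IL7R over all genes, and 1 fell adjusted over the list alone. None of 14 cell cycle, 2 interferon-induced, 1 plasma cell, 2 granulocyte precursor, 1 megakaryocyte and 2 members of each BCL2 family list was called with IL7R, also adjusted over the list alone.

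Of the genes tested with both receptor genes, 92 rose with each and 105 fell with each, against 58.4 and 36.6 for independent lists. In opposite directions, 0 rose with NR3C1 and fell with IL7R and 1 went the other way, against 52.2 and 41. In fits beside the GC slope, a comparison chosen after seeing the data, 0 rose with each and 1 fell with each, against 2.4 and 2.1. In opposite directions there were 0 and 1, against 1.3 and 3.9. NR3C1 and IL7R themselves had r = 0.24 (permutation p = 0.043, adjusted p = 0.072) and rho = 0.29 (permutation p = 0.0123, adjusted p = 0.11), with r = 0.18 without the 2 farthest samples. Their partial r was 0.07 beside the GC slope (permutation p = 0.54), 0.15 beside handling stress and 0.16 beside the first 2 principal components.

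The remaining planned relations missed the threshold after adjustment over 10. NR3C1 had r = -0.26 with the mature T cell score (permutation p = 0.0245, adjusted p = 0.053; rho = -0.20, permutation p = 0.083; r = -0.29 without the 2 farthest samples). IL7R had r = -0.27 with the early progenitor score (permutation p = 0.0189, adjusted p = 0.053; rho = -0.19, permutation p = 0.105; r = -0.18 without the 2 farthest). With the mature T cell score IL7R had r = 0.26 (permutation p = 0.0265, adjusted p = 0.053; rho = 0.13, permutation p = 0.258; r = 0.13 without the 2 farthest). For NR3C1 with the early progenitor and cortical thymocyte scores, r was 0.06 and 0.04 (permutation p = 0.62 and 0.756, adjusted p = 0.89 for both) and rho was 0.02 and 0.08 (permutation p = 0.876 and 0.474). For IL7R with the glucocorticoid-induced and STAT5-induced scores, r was 0.03 and -0.01 (permutation p = 0.803 and 0.908, adjusted p = 0.89 and 0.91) and rho was 0.03 and -0.02 (permutation p = 0.767 and 0.886).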

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

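The covariates GC slope, small RNA share and, except in relations with the glucocorticoid score, handling stress, the filter at mean log2 CPM 4 and rank-based normal scores in camera were chosen after seeing the data. With NR3C1, 3778 genes became 2067 beside the first 2 principal components, 1929 beside handling stress and 1599 beside the GC slope, and stayed between 3173 and 4182 otherwise. With IL7R, 392 genes became 54 after quantile normalization (35 positive and 19 negative, against 207 and 185), 803 beside other cell type scores, 123 beside 2 components, 100 without the 2 farthest samples, 191 beside the small RNA share, 43 beside handling stress and 48 beside the GC slope. The balance of directions turned with NR3C1 beside 2 components (1001 positive and 1066 negative) and the GC slope (609 and 990), against 2220 and 1558. With IL7R it turned beside 2 components (52 and 71), without the 2 farthest samples (37 and 63) and with the filter at mean log2 CPM 4 (165 and 177). Lists called with NR3C1 went from 1 to 0 with an estimated correlation, 0 beside other cell types, 3 with fry, 1 beside 2 components (glucocorticoid-induced genes instead of handling stress), 2 beside the GC slope and 0 beside it with an estimated correlation. With IL7R the 6 lists became 0 with an estimated correlation, 1 with it beside the GC slope, and 4 to 8 otherwise. The r of NR3C1 with the glucocorticoid-induced score passed the threshold beside other cell types (0.423), 2 components (0.426), handling stress (0.548), the GC slope (0.506) and the small RNA share (0.301). IL7R with the cortical score no longer passed after quantile normalization (0.283), without the 2 farthest samples (0.216) or as rho (0.252). IL7R with the mature score passed beside other cell types (0.296), as a median of z scores (0.304), beside handling stress (0.303) and beside the GC slope (0.271). NR3C1 with the mature score and IL7R with the early score passed beside 2 components (-0.281 and -0.303) and beside the GC slope (-0.316 and -0.306), and NR3C1 with the cortical score beside 2 components (0.302). Relations near 0 changed sign. For IL7R with the STAT5 score r was 0.0116 beside other cell types, 0.0140 beside cell cycle, 0.106 beside 2 components, 0.125 beside handling stress, 0.0246 beside the GC slope and 0.0236 beside the small RNA share. For NR3C1 with the early score it was -0.188 beside 2 components and -0.0581 as a median, and with the cortical score -0.0198 without the 2 farthest samples and -0.0346 beside handling stress. Among named genes, sensitivity is given for the leading genes and for list members called in at least 1 setting, except 2 that are not used here, a rule set after seeing the data. Beside the GC slope, slopes with NR3C1 changed sign for JUN (0.0421), JUNB (0.0460), MT1X (0.0112), NCOA1 (-0.0619), HSP90AA1 (0.0193), PTGES3 (-0.239, adjusted p = 0.0200) and MCM6 (-0.384, adjusted p = 0.0357). Beside 2 components they did so for MT1X (0.0113), NCOA1 (-0.0210), HSP90AA1 (0.00935), PTGES3 (-0.122), MCM6 (-0.0890) and DUSP1 (-0.168). Beside other cell types CD3D (0.00698), HHEX (0.119) and IL2RG (0.0127) changed sign with NR3C1, as did HHEX (0.0629), IL2RG (0.0462) and MCM6 (-0.0432) beside handling stress, and CD3D (0.0354) and IL2RG (0.0146) without the 2 farthest samples. CD3D also did beside cell cycle (0.0282), without the 8 samples (0.00995) and with normal scores (0.0325). With IL7R, BCL11B changed sign after quantile normalization (-0.00198), without the 2 farthest samples (-0.0938) and with normal scores (-0.176), and TYMS beside other cell types (0.0456), without the 8 samples (0.0206) and with normal scores (0.0120). Of 125 list members, 57 with NR3C1 and 104 with IL7R were called in no setting, and 42 and 48 of these changed sign in at least 1. For the changes above the cause was not tested. The median gene SD was 0.707 after quantile normalization, against 0.747. Leaving out the filter changed nothing, since it removed 0 genes. The alternatives for BCL2 and BCL2L11 were not run. Spearman rho, planned for the list tests, was not run, and camera on normal scores stood in for it. Depth is unknown, so what it limits cannot be stated. No paired analysis was possible because there is 1 group.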

Other observations

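Most tests in this part were chosen after the main results were seen, while the other cell type scores as covariates of the gene counts were planned. Only the prediction for thymocyte stage was written before its own value was known. Early progenitor and cortical thymocyte scores opposed each other across the 75 samples (r = -0.64, permutation p = 1e-05, the smallest possible; rho = -0.61, permutation p = 1e-05; r = -0.63 without the 2 farthest samples; adjusted p = 3e-05 and 2.6e-05 over 21 relations). Cell cycle genes went with the cortical score (r = 0.56, permutation p = 1e-05; rho = 0.62, permutation p = 1e-05; r = 0.61 without the 2 farthest; adjusted p = 3e-05 and 2.6e-05) and against the early score (r = -0.46, permutation p = 3e-05; rho = -0.43, permutation p = 0.0001; r = -0.42 without the 2 farthest; adjusted p = 6.3e-05 and 0.00023). CD1B and ZBTB16 were opposed (r = -0.49, permutation p = 2e-05; rho = -0.52, permutation p = 1e-05; r = -0.59 without the 2 farthest; adjusted p = 4.7e-05 and 2.6e-05). Among glucocorticoid-induced genes TSC22D3 and PER1 varied together (r = 0.74, permutation p = 1e-05; rho = 0.74, permutation p = 1e-05; r = 0.73 without the 2 farthest; adjusted p = 3e-05 and 2.6e-05). FKBP5, another canonical target, had r = 0.09 with PER1 (permutation p = 0.459; rho = -0.03, permutation p = 0.83; r = 0.00 without the 2 farthest; adjusted p = 0.46 and 0.83). With TSC22D3 it had r = 0.23 (permutation p = 0.0535; rho = 0.19, permutation p = 0.0948; r = 0.23 without the 2 farthest; adjusted p = 0.065 and 0.10), and 0.30 beside the GC slope (permutation p = 0.0101).

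The first pattern is the number of genes associated with each receptor gene. For NR3C1, 1 of 100 orderings of its values, the real one included, gave as many genes (3778, against 1192 in the highest of the others). For IL7R 3 of 100 did (392, against 550). Chance is argued against at 0.05 for each count, unadjusted for the 2 tests and more weakly for IL7R. The lower IL7R counts in other settings were not tested in this way. Genes matched on mean and SD gave a median of 4799 calls when used in place of NR3C1 and 2854.5 in place of IL7R, so neither receptor gene stood out. The other cell type scores hold 1 to 5 genes each and none for normal T cells, so they cannot decide about RNA of other marrow cells as such. Of the 3778 NR3C1 calls, 3229 stayed called beside these scores, so the signal in those few genes does not account for most of the calls. A GC trend may account for a part of them, since 505 stayed called beside the GC slope. NR3C1 itself had r = -0.57 with that slope, which widens the error in this fit. The lost calls alone therefore do not show how far the relations shrank. The first principal component (23.1% of variance) had r = -0.95 with the GC slope (permutation p = 1e-05, and r = -0.94 without the 2 farthest). Its rho was -0.91 (permutation p = 1e-05), with adjusted p = 3e-05 for r and 2.6e-05 for rho. The GC slope also went with the handling stress score (r = 0.59, permutation p = 1e-05; rho = 0.65, permutation p = 1e-05; r = 0.57 without the 2 farthest; adjusted p = 3e-05 and 2.6e-05), the erythroid score (r = 0.37, permutation p = 0.00108; rho = 0.35, permutation p = 0.00226; r = 0.40 without the 2 farthest; adjusted p = 0.0017 and 0.0037) and the monocyte score (r = 0.30, permutation p = 0.00923; rho = 0.24, permutation p = 0.0376; r = 0.30 without the 2 farthest; adjusted p = 0.012 and 0.049). No batch is labelled and no biological explanation was tested, so an origin of the slope in library preparation, in sample handling or in the cells remains open.

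The second pattern is that NR3C1 goes with glucocorticoid-induced genes once the GC slope is taken into account. The partial r of 0.51 against the plain 0.29 decides nothing about a GC trend, since the pattern was picked from that difference. The correction did not raise r for lists in general. Over 10000 random lists matched on mean level and GC content, the median r was 0.01 plain and -0.05 beside the GC slope. Of these lists 9.27% reached the plain r and 0.03% the partial r. Those shares decide nothing about the relation itself, since it was picked for its high partial r. The random lists were also not matched on the correlation between members. The handling stress score went against NR3C1 (r = -0.40, permutation p = 0.00038; rho = -0.43, permutation p = 0.00014; r = -0.40 without the 2 farthest; adjusted p = 0.00067 and 0.00029; -0.10 beside the GC slope, permutation p = 0.387) and with the glucocorticoid-induced score (r = 0.42, permutation p = 0.00018; rho = 0.40, permutation p = 0.00042; r = 0.35 without the 2 farthest; adjusted p = 0.00034 and 0.0008; 0.37 beside the GC slope, permutation p = 0.00088). As a covariate it could therefore only keep or raise r, so the partial r of 0.59 beside it and the GC slope (permutation p = 1e-05) decides nothing about sample handling. A hypothesis is that receptor abundance, or steroid exposure before sampling, may set part of the spread of these targets, which was not tested, and exposure is not analysed here.

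The third pattern is IL7R with the 7 measured NOTCH1-induced genes, without HES1, HEY1, DTX1 or NRARP. A GC trend is argued against by a partial r of 0.52 (permutation p = 1e-05). Without CR2 and beside the other cell type scores, the partial r was 0.46 (permutation p = 8e-05). It was 0.26 there without the 2 farthest samples (permutation p = 0.0281). This does not decide about other marrow cells, B cells included, since the scores hold 1 to 5 genes each, and 2 for B cells. The immunoglobulin segment IGHV4-34 kept a slope of 0.63 on IL7R beside these scores (limma adjusted p = 0.0038). Thymocyte stage is argued against by a partial r of 0.44 beside 3 stage scores (permutation p = 9e-05). Without the 2 farthest samples it was 0.31 (permutation p = 0.008). The 2 samples with the most extreme IL7R levels carry part of the relation. Beyond thymocyte stage and other marrow cells, no biological explanation was tested. A hypothesis is that shared NOTCH1 activity may underlie the relation, since IL7R is a known NOTCH1 target in T cells, and NOTCH1 mutations, which could decide it, are not analysed here.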
